A study of Mus musculus with 12 samples.

How the data were processed

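RNA from whole livers of wild type and interleukin-18 knockout BALB/c mice, taken at 6 and 12 weeks of age, was measured on 12 arrays, 3 in each of 4 groups. Per the labels' protocols, total RNA was extracted from livers kept in a stabilising solution, copied into cyanine 3-labelled cRNA with an oligo-dT primer carrying a T7 promoter, and hybridised to 1-colour mouse arrays. The labels name the arrays of a group as biological replicates. They state neither the sex of the animals nor the time of day at which they were killed.

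Per the file headers, the authors quantified each array with Agilent Feature Extraction 10.7.3.1, which wrote a processed signal, an intensity from which a spatially fitted background had been subtracted, then detrended multiplicatively, with low values replaced by a surrogate, and which was not scaled between arrays. The mean spot intensity and the local background median, also deposited by the authors, are raw scanner values. The deposited value table of the series held the same processed intensity rounded to 3 significant digits: over 62976 spots per array the largest difference from the scanner value was 0.497%, so its scale is linear, its values are not centred and they carry no ratio with a direction. The medians of its columns ran from 21.6 to 29.5. Probe positions are those of the files, on mm9.

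The arrays held 55681 distinct probes outside the controls. A RefSeq gene table on GRCm38 gave current symbols to 26582 probes through an accession, 2602 probes already carried a current symbol, 492 were renamed through a synonym and 26005 kept the name in the file. No coordinate was taken from that table. Control spots and spots marked as outliers were left out, and spots of a probe were averaged on the log2 scale. The level of a probe was log2 of the processed signal minus the array's 75th percentile. A probe was tested where it was well above background on all 3 arrays of at least 1 group, which 29791 probes (53.5%) were. For the 5432 genes with more than 1 such probe, the probe with the highest mean over the 12 arrays was taken, which left 22116 genes. The signal behind each array is described by its 75th percentile, from 349 to 420 in scanner units, and by the share of spots well above background, from 50.1% to 57.7%. The number of arrays limits the precision.

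Group means were fitted in 1 model over the 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual degrees of freedom, prior degrees of freedom 2.23). The contrasts were knockout against wild type at each age, the average of these, 12 against 6 weeks in each genotype, and the difference of the genotype differences (12 minus 6 weeks). Every adjusted p is limma's with the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05, unless a list test is named. Errors of log2 differences are standard errors of that fit. The 34 gene lists, holding 606 gene entries, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry, a rotation test of whether the genes of a list move one way on balance. The 6 missing values took their group's mean in the list tests.

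Where a gene was not well above background on any array of its dimmer group, its fold is given as "at least": the mean of the brighter group against the dim group's mean of, per array, the higher of the lowest signal of a probe well above background and the probe's own signal.

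The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took, per contrast, the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap (at both ages for the average), and the 5 largest in each direction for the difference between ages. Names that are only an accession, an array identifier, a clone or a predicted gene were left out of it. It also took up to 4 members of each list with the smallest p, Il18 itself, and passing members of the lists of Il18 neighbours and of pancreas, adipocyte and erythroid markers. Genes named outside the rule are marked as chosen after their values were seen. Some genes that the rule took are not reported here.

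The array files gave 2 slides, each scanned apart. Slide 1 held the 3 wild type arrays of 6 weeks and replicate 1 of the 12-week wild type. Slide 2 held replicates 2 and 3 of the 12-week wild type and all knockout arrays. At 6 weeks the slide therefore separates the genotypes, and a fit with the slide as a block rests on replicate 1 of the 12-week wild type. At 12 weeks the genotypes can be set against each other within slide 2, where the wild type arrays and the knockout arrays lay in different rows. The 75th percentile of the signal ran from 411 to 420 on slide 1 and from 349 to 393 on slide 2. Surrogates stood for 25.4% to 30.9% of spots in the 6-week wild type and 19.3% to 24.3% on the other arrays.

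The fit and the list test were tested on simulated data with the means and spreads of the real genes. For knockout against wild type at 6 weeks, with 200 of 22116 genes changed in sets of 50, the fit recovered 30% of those changed 1.5-fold, 68% of those changed 2-fold, 88% of those changed 4-fold and 100% of those changed 8-fold. Of the 152 genes it called, 9 (5.92%) were unchanged in the simulation. For the 12-week comparison, camera called 0 of 30 unchanged lists, and the 1 list of 20 genes that had been shifted passed with an adjusted p of 3.66e-29. The simulated genes were drawn independently of each other. The simulation therefore cannot show how often camera calls unchanged lists whose genes are correlated.

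Alternatives covered quantile normalization, normexp background correction with an offset of 50, other filters on dim probes, other ways to choose a gene's probe, an intensity trend with robust variances, only the groups compared, the slide as a fixed and as a random block, the replicate number as a block, the deposited value table, a 1.5-fold minimum and leaving out each array in turn. Fits on the arrays of slide 2 alone and of slide 1 alone were added after seeing the data. Figures were drawn with matplotlib 3.10.9.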

Results

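Gene expression was compared between livers of wild type mice and of mice lacking interleukin-18, a cytokine of the interleukin-1 family that is matured by inflammasome caspases and known for driving interferon-gamma production. The design crossed genotype with age, 6 and 12 weeks, and each of the 4 groups held 3 arrays. The arrays gave values for 22116 genes. Across genes, which are not independent replicates, arrays of a group correlated at 0.987 to 0.996 and arrays of different groups at 0.981 to 0.992. The first principal component, with 32.7% of the variance, placed the 6-week wild type arrays between -51.2 and -48.7 and the other 9 arrays between -7.81 and 28.6. The 6-week wild type arrays all lay on slide 1 and all knockout arrays on slide 2. The 12-week wild type had replicate 1 on slide 1 and replicates 2 and 3 on slide 2. Its replicate 1 had the value of -7.81. On this component all arrays of slide 1 thus had negative values and all arrays of slide 2 positive ones. The component therefore separates the slides as well as the 6-week wild type from the rest.

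Il18, the targeted gene, was measured with 1 probe, at chromosome 9 from 50389761 to 50389820 on mm9. Its log2 level relative to the array's 75th percentile was 2.40 ± 0.05 (SD, n = 3) in the 6-week wild type and 2.30 ± 0.18 (SD, n = 3) in the 12-week wild type, against -0.14 ± 0.19 (SD, n = 3) and -0.04 ± 0.08 (SD, n = 3) in the knockout at 6 and 12 weeks. Every knockout array lay below every wild type array. Averaged over both ages, Il18 was lower in the knockout by 5.42-fold (log2 difference -2.44 ± 0.08, SE, adjusted p = 2.82e-07), and with the slide as a block the difference was -2.48. The probe stayed well above background in the knockout, and which part of the gene was deleted is not given in the sources used here.

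**Figure D1:**
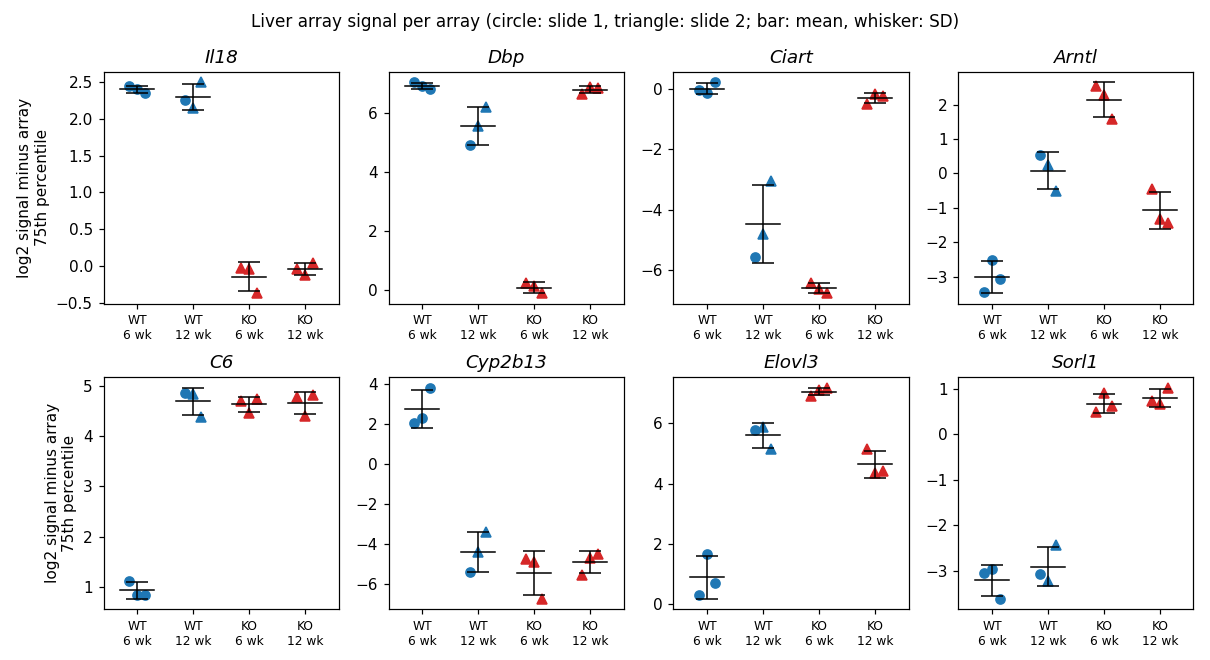
Signal of 8 genes on each array, as log2 of the processed signal minus the array's 75th percentile, by genotype (blue, wild type WT; red, knockout KO) and age; circles are arrays of slide 1, triangles of slide 2, bars the mean and whiskers the SD of 3 arrays. Il18 lies between 2.15 and 2.49 in wild type and between -0.37 and 0.04 in the knockout, while Dbp is low in the 6-week knockout and Cyp2b13 is high and C6 low in the 6-week wild type.

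At 6 weeks, livers without interleukin-18 differed from wild type most, by list median, in sex-biased liver genes and in genes of the circadian clock. Elovl3, a fatty acid elongase with male-biased expression in mouse liver, was 71.4-fold higher in the knockout (6.16 ± 0.34, SE, n = 3 per group, adjusted p = 9.47e-06). The female-biased cytochrome P450 genes Cyp2b13 and Cyp2b9 were at least 146-fold and at least 63.5-fold lower, with Cyp2b13 well above background on 0 arrays of the knockout. Dbp, a transcription factor under clock control, was 113-fold lower (-6.82 ± 0.26, adjusted p = 6.28e-07), and Arntl, which encodes the clock activator BMAL1, was 35.6-fold higher (5.15 ± 0.38). Cdkn1a, which encodes the cell cycle inhibitor p21, was at least 40.5-fold higher.

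Of 14 male-biased genes measured, 12 were higher in the 6-week knockout and 0 lower (13 higher when adjusted over the list alone). C6, a complement component gene, rose by 3.71 ± 0.16 on the log2 scale and Cyp7b1, an oxysterol hydroxylase gene, was 12.1-fold higher. The male-biased list passed camera with an adjusted p of 1.72e-11 (adjusted p = 0.0749 with an estimated correlation). Of 13 female-biased genes, 11 were lower and 0 higher (12 lower when adjusted over the list alone). Hao2, a peroxisomal hydroxyacid oxidase, was at least 12.9-fold lower. The female-biased list passed with an adjusted p of 1.45e-10 (adjusted p = 0.0596 with an estimated correlation).

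Of 19 clock genes, 4 were higher and 11 lower in the 6-week knockout (5 and 12 when adjusted over the list alone), with an adjusted p of 0.00298 for the list (adjusted p = 0.426 with an estimated correlation). Nfil3, a repressor that acts opposite Dbp, rose by 2.80, whereas Tef fell by 2.80 and Usp2, a rhythmic deubiquitinase gene, fell by 4.48 on the log2 scale. Ciart, a clock repressor, was at least 21.9-fold lower.

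Xenobiotic metabolism genes numbered 2 higher and 13 lower of 23 (3 and 15 when adjusted over the list alone), led by Cyp2b10 at -5.70 ± 0.60 and the aldo-keto reductase gene Akr1b7 at -2.26, with an adjusted p of 4.17e-06 for the list (adjusted p = 0.674 with an estimated correlation). Among 30 targets of PPAR-alpha and genes of fatty acid oxidation, 1 was higher and 8 lower (1 and 10 when adjusted over the list alone): the fatty acid hydroxylase genes Cyp4a14 and Cyp4a10 differed by -3.86 and -2.23, while Pdk4, a kinase that restrains pyruvate oxidation, rose by 2.36. That list passed with an adjusted p of 0.0393 (adjusted p = 0.974 with an estimated correlation). The unfolded protein and integrated stress response list had 11 genes higher and 1 lower of 21 (the same counts when adjusted over the list alone), among them the chaperone genes Pdia6 at 0.91 and Sdf2l1 at 1.73, with an adjusted p of 0.00173 (adjusted p = 0.674 with an estimated correlation). Of 23 cell cycle genes, 7 were higher and 2 lower (10 and 2 when adjusted over the list alone), with Ccna2 at 1.56 and Ccne1 at -1.43 and an adjusted p of 0.0267 for the list (adjusted p = 0.974 with an estimated correlation). The other 27 lists did not pass camera with the preset correlation at 6 weeks. Of these, fry called the erythroid markers, with 4 higher and 1 lower of 6 and a median of 0.50 (adjusted p = 0.00509). It also called the neutrophil and monocyte markers, with 3 higher and 2 lower of 9 (adjusted p = 0.0188). The PPAR-alpha and cell cycle lists did not pass fry (adjusted p = 0.233 and 0.18). Blocking on the slide gave 8 male-biased genes higher with a list median of 1.29 and 5 female-biased genes lower with -2.80. It gave 4 clock genes higher and 9 lower with a median of -1.39, 5 xenobiotic genes lower with -0.73 and 3 PPAR-alpha targets lower with -0.30. These 5 lists still passed. The unfolded protein list, with 1 gene higher and a median of 0.32, and the cell cycle list, with 1 gene lower and a median of 0.01, did not (adjusted p = 0.253 and 0.516).

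In all, 4658 genes passed at 6 weeks, 2591 higher and 2067 lower in the knockout, and 948 of them differed at least 2-fold. The named rises also included Serpina12, Scara5, Nat8f5, Sorl1, Tubb2a and Grk5, and the named falls Slc22a29, Acot3 and Slc22a27. The 2 probes of Scara5 differed, at 4.66 and 0.18, and only the first passed, a fitted value since 0 wild type arrays were well above background. With the slide as a fixed block, a fit that rests on 1 wild type array, 589 genes passed, and with the slide as a random block 1226; no value can be had within a slide, as each slide held only 1 genotype at this age. In the fixed block fit Elovl3, Dbp, Arntl, Cdkn1a and C6 still passed. Acot3 at -6.02, Scara5 at a fitted 4.36 and Slc22a29 at -5.78, with 1 knockout array well above background, did not (adjusted p = 0.0534, 0.156 and 0.0819). Leaving out single arrays gave 2617 to 3138 genes.

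At 12 weeks the knockout livers differed from wild type in single genes of glucose metabolism and the cell cycle and in lists of clock, lipid and lymphocyte genes. These lists passed camera with the preset correlation, and none of them passed with an estimated one. Igfbp1, an insulin-repressed binding protein gene, was 6.31-fold lower in the knockout (-2.66 ± 0.44, SE, n = 3 per group, adjusted p = 0.00794), and G6pc, which encodes the catalytic subunit of glucose-6-phosphatase, fell by 1.76 on the log2 scale. Pfkfb1, which controls glycolysis, rose by 1.41. Ciart, well above background on 1 of 3 wild type arrays, rose by 4.16 ± 0.48 and Usp2 by 2.67 ± 0.29. Ccnd1, which encodes cyclin D1, was 4.28-fold lower (-2.10 ± 0.30, adjusted p = 0.00443).

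Of 14 markers of NK and T cells, 4 were lower and 0 higher at 12 weeks (5 lower when adjusted over the list alone). They were Cd3g at -1.77, Cd4 at -0.96, Ccl5 at -0.89 and Il2rb at -0.85, of which Cd3g lies 5.61 Mb from Il18. The list, with a median of -0.42, passed with an adjusted p of 0.000105 (adjusted p = 0.52 with an estimated correlation). Within slide 2, where the median was -0.50, Cd3g passed at -1.83, and Cd4 at -0.75, Ccl5 at -0.92 and Il2rb at -0.75 did not (adjusted p = 0.0844, 0.0932 and 0.149). Of 16 Kupffer cell and macrophage markers 3 were lower (3 when adjusted over the list alone), with Cd14 at -0.70 and Folr2 at -0.53 and an adjusted p of 0.000537 for the list (adjusted p = 0.588 with an estimated correlation). Of 15 genes of interleukin-18 and inflammasome signalling 2 were lower (4 when adjusted over the list alone), Il1b at -1.86 and Il6, which was at least 1.53-fold lower, with an adjusted p of 0.018 (adjusted p = 0.588 with an estimated correlation). Of 26 interferon-gamma response genes 3 were lower (3 when adjusted over the list alone), among them Gbp4 at -0.96, with an adjusted p of 0.018 (adjusted p = 0.751 with an estimated correlation). Jchain, the immunoglobulin joining chain gene, was the 1 marker of B and plasma cells among 9 that passed (1 when adjusted over the list alone), at -1.49, and that list had an adjusted p of 0.0341 (adjusted p = 0.588 with an estimated correlation).

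Fatty acid synthesis had 3 genes higher and 0 lower of 21 at 12 weeks (5 higher when adjusted over the list alone), among them Thrsp at 1.69 and Pklr at 0.73. The list had an adjusted p of 0.00167 (adjusted p = 0.588 with an estimated correlation). Lipid droplet genes numbered 2 higher of 12 (3 when adjusted over the list alone), Mogat1, a monoacylglycerol acyltransferase gene, at 1.60 and Cidec, a lipid droplet protein gene, at 1.57, with an adjusted p of 0.0305 (adjusted p = 0.588 with an estimated correlation). Of the 19 clock genes 9 were higher and 0 lower (9 and 1 when adjusted over the list alone), including Per2 at 1.91 and Per3 at 1.87, with an adjusted p of 0.00438 (adjusted p = 0.52 with an estimated correlation). The time of killing is not in the labels for either age. Periportal hepatocyte genes numbered 3 higher and 1 lower of 9 (6 and 1 when adjusted over the list alone), with the serine dehydratase gene Sds at 1.16 and an adjusted p of 0.00842 for the list (adjusted p = 0.52 with an estimated correlation). Of 6 erythroid markers 2 were higher (5 when adjusted over the list alone), Klf1 at 1.26 and Slc4a1 at 0.46, with an adjusted p of 0.01 (adjusted p = 0.52 with an estimated correlation). Lists of cell cycle, xenobiotic metabolism and acute phase genes passed with a negative shift, with medians of -0.39, -0.24 and -0.15, and those of the unfolded protein response and of oxidative phosphorylation with a positive one, with medians of 0.49 and 0.10. None of these 5 passed with an estimated correlation (adjusted p = 0.621, 0.588, 0.751, 0.588 and 0.751). Of cell cycle genes 1 was higher and 3 lower (1 and 4 when adjusted over the list alone), of xenobiotic genes 4 were lower (6 when adjusted over the list alone), and of unfolded protein genes 3 were higher (8 higher and 1 lower when adjusted over the list alone). A fixed slide block, which gives the medians of slide 2 alone, gave medians of -0.50 for NK and T cell markers, -0.36 for Kupffer cell markers, -0.24 for interleukin-18 and inflammasome genes, -0.23 for interferon-gamma response genes, 0.33 for fatty acid synthesis, 0.42 for clock genes, 0.37 for periportal genes, 0.69 for erythroid markers, -0.51 for the cell cycle, -0.26 for xenobiotic metabolism, -0.17 for the acute phase and 0.38 for the unfolded protein response. In that fit the lists of B cell markers, lipid droplet genes and oxidative phosphorylation did not pass, with medians of -0.23, 0.35 and 0.08 (adjusted p = 0.108, 0.165 and 0.24), and within slide 2 alone the unfolded protein list did not pass either (adjusted p = 0.06). The block gave 3 NK and T cell markers, 2 Kupffer cell markers, 1 interferon-gamma response gene and 5 cell cycle genes lower. It gave 1 erythroid marker, 1 fatty acid synthesis gene, 1 lipid droplet gene, 7 clock genes and 2 periportal genes higher. Of 21 unfolded protein genes 0 passed with the block and 0 within slide 2. Within slide 2 there were 3 clock genes higher, 4 cell cycle and 2 xenobiotic genes lower, and 0 in the Kupffer cell, interferon-gamma and erythroid lists. With fewer arrays there, Thrsp at 1.49, Pklr at 0.73, Cd14 at -0.74, Folr2 at -0.60 and Gbp4 at -1.09 did not pass (adjusted p = 0.126, 0.114, 0.0655, 0.0757 and 0.0858). Il1b at -1.69, Klf1 at 1.34, Slc4a1 at 0.46 and Per3 at 1.70 did not pass either (adjusted p = 0.0599, 0.0579, 0.0892 and 0.0624).

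In all, 1815 genes passed at 12 weeks, 1249 higher and 566 lower in the knockout, of which 262 differed at least 2-fold. The named rises were those of Erdr1, at 5.76 ± 0.30, Flacc1, at least 4.30-fold higher, Fmr1nb, Ciart, Sorl1, Lrtm1, Usp2, Krtap4-16, Apoa4 and Dkk4. The named falls were in Nxpe4, Igfbp1, Col5a3, Il18, Cmtm2a, Nr4a1, Klhl1, Slc38a5, Ccnd1 and Msmp. Of the 2 probes of Krtap4-16, of Cidec and of Cd4 only 1 passed, and the others lay at -0.04, 0.80 and -0.68. With the slide as a block 1281 genes passed and within slide 2, with 2 wild type and 3 knockout arrays, 747. Within slide 2 Erdr1, Ciart, Usp2 and Ccnd1 still passed. Igfbp1 at -2.50 and Fmr1nb at 3.62, against 4.25 with all arrays, did not (adjusted p = 0.0599 and 0.0701), and Fmr1nb was well above background on 1 wild type array of this age. Klhl1 at -2.53 and Slc38a5 at -2.09 did not pass within slide 2 either (adjusted p = 0.0634 and 0.0576). Leaving out single arrays gave 681 to 2069 genes.

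**Figure D2:**
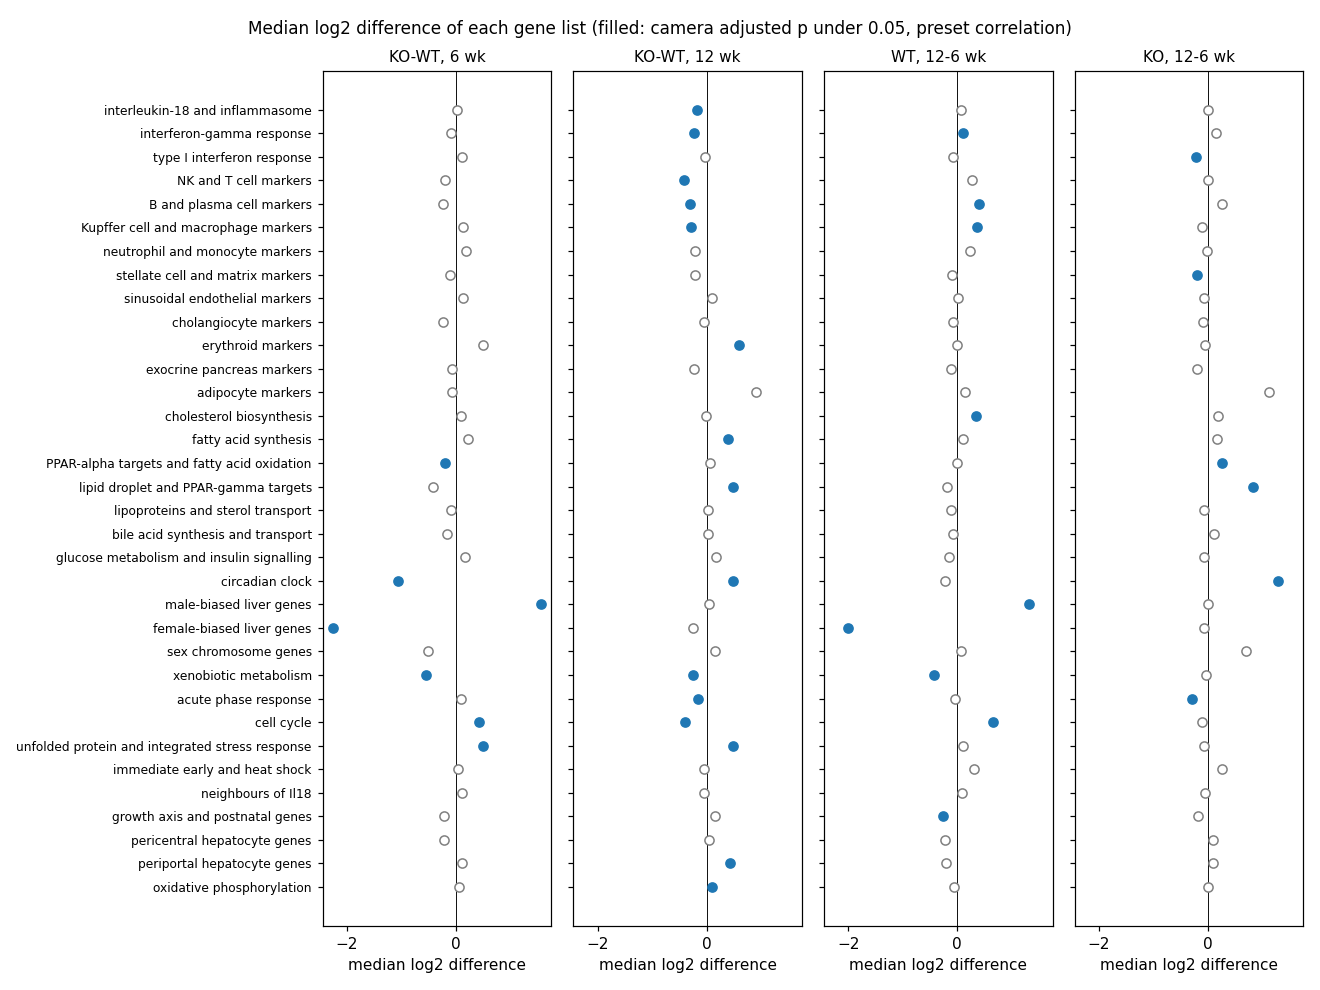
Median log2 difference of the measured genes of each list (rows) in 4 comparisons (panels, with a shared horizontal axis); filled points passed camera with the preset correlation. The lists of male-biased and female-biased liver genes lie farthest from 0 in the comparison of genotypes at 6 weeks (medians 1.56 and -2.25) and in that of ages within wild type (1.31 and -2.01).

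Averaged over both ages, the knockout livers were higher in Sorl1, Apoa4 and Fxyd6 and lower in Cyp2b10, Nxpe4 and Il18. Cyp2b10 lay at least 1.72 log2 units higher on each 6-week wild type array than on any array of the other groups. Within slide 2 at 12 weeks its difference of -1.97 ± 0.72 (SE) did not pass (adjusted p = 0.173). Sorl1, a sorting receptor gene, rose 14-fold (3.81 ± 0.16, SE, adjusted p = 1.06e-06) by the probe used, while its other probe passed at 1.33. Apoa4, an apolipoprotein gene, rose 6.35-fold (2.67 ± 0.19) and Fxyd6, a regulator of ion transport, rose 5.92-fold (2.56 ± 0.09). Tmem25 fell by 2.51 on the log2 scale. Nxpe4, well above background on 0 knockout arrays, was at least 1.26-fold lower at 6 weeks and at least 1.87-fold lower at 12 weeks. These 5 genes lie on chromosome 9 within 9 Mb of Il18, at distances of 8.61 Mb for Sorl1, 4.34 for Apoa4, 5.19 for Fxyd6, 5.79 for Tmem25 and 2.18 for Nxpe4.

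Of 28 measured neighbours of Il18, 5 were higher and 6 lower on average over ages (6 and 6 when adjusted over the list alone). As a list they did not pass (adjusted p = 0.729), and the test pointed down where the median of 0.03 and the mean of 0.11 lay above 0. At each age Tex12, a meiosis gene 0.0243 Mb away, was higher (2.29 and 1.88), and Bco2, a carotenoid-cleaving dioxygenase gene 0.0485 Mb away, was lower (-1.49 and -1.31). Of 21 fatty acid synthesis genes 6 were higher and 0 lower (10 when adjusted over the list alone), led by Scd1 at 0.81 and Acacb at 1.18, with an adjusted p of 0.00142 (adjusted p = 0.81 with an estimated correlation). Of 23 xenobiotic genes 11 were lower (14 lower and 1 higher when adjusted over the list alone), with an adjusted p of 2.34e-08 (adjusted p = 0.394 with an estimated correlation). NK and T cell markers numbered 5 lower of 14 (8 when adjusted over the list alone), with an adjusted p of 0.000445, and the unfolded protein list 12 higher and 1 lower of 21 (12 and 2 when adjusted over the list alone), also with 0.000445; for each of these 2 lists the adjusted p = 0.394 with an estimated correlation. Lists of B cell, erythroid, male-biased, female-biased and periportal genes passed as well, with medians of -0.27, 0.48, 0.89, -1.20 and 0.27 (adjusted p = 0.681, 0.394, 0.206, 0.0904 and 0.394 with an estimated correlation). The averages of the male-biased and female-biased lists cover medians of 1.56 and -2.25 at 6 weeks and of 0.04 and -0.25 at 12 weeks, where neither list passed (adjusted p = 0.829 and 0.289), and the difference between ages passed for both. In the fit with a fixed slide block the medians were 0.17 for fatty acid synthesis and -0.09 for B cell markers, which no longer passed (adjusted p = 0.151 and 0.237), and 0 genes of either list did. The other lists passed. They had 3 xenobiotic genes lower with a median of -0.50, 1 NK or T cell marker lower with -0.27, 1 unfolded protein gene higher with 0.40 and 1 erythroid marker higher with 0.69. There were also 7 male-biased genes higher with 0.71, 3 female-biased genes lower with -1.38 and 0 of 9 periportal genes in either direction with 0.30.

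In all, 4547 genes passed on average over ages, 2811 higher and 1736 lower. The named rises also held Krtap4-16, Erdr1, Lad1, Camk2b, Sult5a1, Dkk4 and Plcd3, and the named falls Dbp, Tafa2, Rad51b, Abcd2, Slc35f2 and Cyp3a44. The other probe of Krtap4-16 lay at -0.11 and did not pass. The average covers opposite directions for Erdr1, at -1.11 at 6 weeks and 5.76 at 12 weeks, and for Dbp, at -6.82 and 1.23. With the slide as a fixed block 392 genes passed, 191 higher and 201 lower, and as a random block 986; Sorl1, Apoa4, Fxyd6, Nxpe4 and Tmem25 passed in the fixed block fit, while Camk2b at 2.26, Dkk4 at 2.07, Abcd2 at -2.39, Slc35f2 at -2.25 and Cyp3a44 at -1.40 did not (adjusted p = 0.0975, 0.0961, 0.058, 0.0699 and 0.195), the last pair fitted values since both were well above background on 0 arrays of the 6-week knockout. The comparisons at 6 and at 12 weeks share no arrays; 216 genes were higher in the knockout at both ages (146 for independent lists) and 127 lower at both (52.9 for independent lists), while 95 were higher at 6 weeks and lower at 12 weeks (66.3) and 157 the reverse (117).

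**Figure D3:**
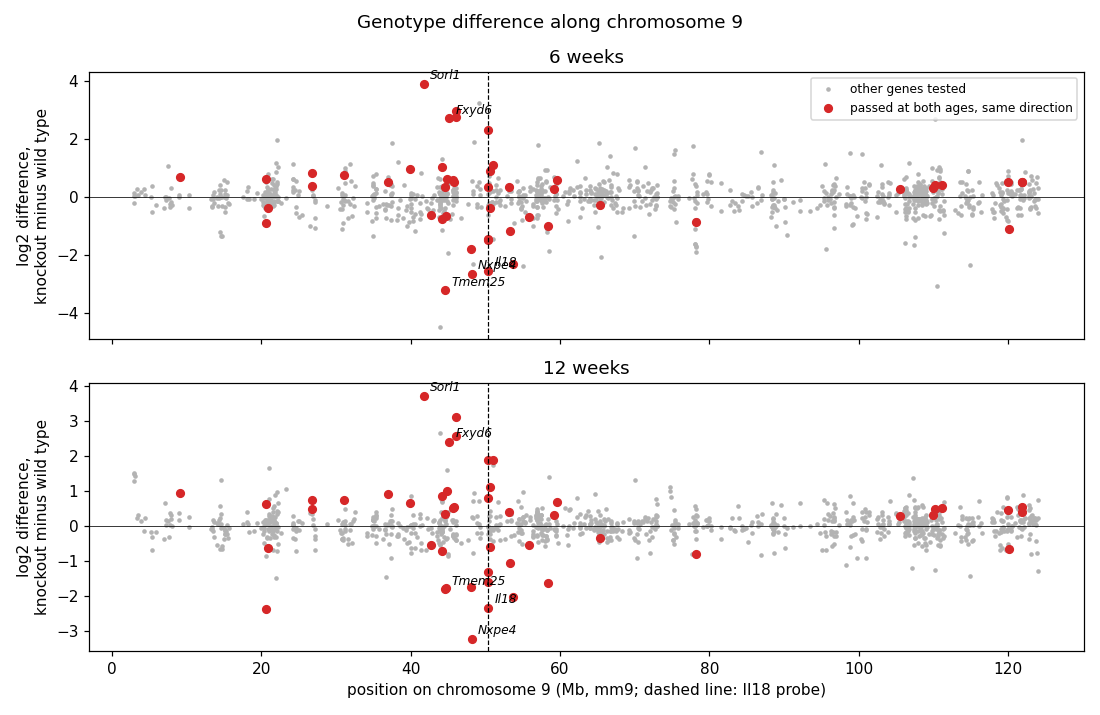
Difference between knockout and wild type (log2) of each gene tested on chromosome 9 against its position (Mb, mm9), at 6 weeks (top) and 12 weeks (bottom); red points passed at both ages in the same direction, and the dashed line marks the Il18 probe. Within 5 Mb of Il18, 16 of 103 genes passed at both ages in the same direction, against 9 of 397 genes more than 40 Mb away on this chromosome.

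Between 6 and 12 weeks, wild type livers gained male-biased and lost female-biased transcripts. Cyp2b13 was 144-fold lower at 12 weeks (-7.17 ± 0.67, SE, n = 3 per group, adjusted p = 0.000327), and was well above background on 2 of the 3 arrays of that age, and Hao2 was lower as well. Elovl3 was 26.1-fold higher (4.70 ± 0.34) and Cyp7b1 9.37-fold higher. Igf2bp3, an RNA-binding protein gene of fetal tissue, was at least 5.71-fold lower.

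Of 14 male-biased genes 12 were higher (12 when adjusted over the list alone) and of 13 female-biased genes 9 were lower at 12 weeks (9 when adjusted over the list alone). These 2 lists passed with adjusted p of 3.18e-15 and 1.77e-09 and were the only ones in the series that passed with an estimated correlation, each with an adjusted p of 0.0414. Of 23 cell cycle genes 9 were higher (12 when adjusted over the list alone), with Ccnb1 3.99-fold higher and Cdc20 at 2.39, a list median of 0.65 and an adjusted p of 7.12e-07 (adjusted p = 0.775 with an estimated correlation). Of 25 cholesterol biosynthesis genes 4 were higher (8 higher and 1 lower when adjusted over the list alone), with Fdps at 1.33 and Cyp51 at 1.06 and an adjusted p of 0.00552 (adjusted p = 0.806 with an estimated correlation). Among 26 interferon-gamma response genes 4 were higher and 1 lower (6 and 1 when adjusted over the list alone); those higher included H2-Aa at 1.52, H2-Ab1 at 1.41 and Cd74 at 1.24, which serve antigen presentation, with an adjusted p of 0.0243 (adjusted p = 0.806 with an estimated correlation). Lists of Kupffer cell, B cell, xenobiotic and growth axis genes passed with medians of 0.36, 0.40, -0.42 and -0.25 (adjusted p = 0.806, 0.775, 0.806 and 0.775 with an estimated correlation). A fixed slide block gave 9 male-biased genes higher with a median of 1.31, 7 female-biased genes lower with -1.82, 1 cell cycle gene higher with 0.21 and 1 B cell marker higher with 0.40. It gave 2 xenobiotic genes higher and 5 lower with a median of -0.58 and 1 growth axis gene lower with -0.33. These 6 lists passed. Those of cholesterol biosynthesis, interferon-gamma response and Kupffer cell genes, at 0.14, 0.12 and 0.25 and with 0 genes each, did not (adjusted p = 0.303, 0.119 and 0.0649).

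In all, 1997 genes passed between ages in wild type, 1019 higher and 978 lower at 12 weeks. The named rises also held Nat8, C6, Irx1, Nat8f5, Scara5, Serpina12, Lad1 and Lrp2, and the named falls Erdr1, Slc22a26, Cyp2b9, Slc22a27, Slc22a29 and Ciart. The other probe of Scara5 lay at 0.27 and did not pass. With the slide as a fixed block 728 genes passed, and as a random block 1077. Within slide 1 the comparison sets 3 arrays against 1, so a count of genes from it is not given. Leaving out single arrays gave 989 to 3901 genes, the highest without replicate 1 of the 12-week wild type, the array on slide 1.

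Between 6 and 12 weeks, knockout livers changed in lists of clock and lipid droplet genes, in a comparison that lay wholly on slide 2. Both lists passed camera with the preset correlation, and neither passed with an estimated one. Dbp was 104-fold higher at 12 weeks (6.70 ± 0.26, SE, n = 3 per group, adjusted p = 1.17e-06), Ciart at least 17.7-fold higher and Per3 at least 4.41-fold higher, while Arntl was 9.26-fold lower and Npas2, which encodes a paralogue of CLOCK, was at least 2.25-fold lower. Igfbp1 was 19.4-fold lower (-4.28 ± 0.44) and G6pc 5.84-fold lower. Cdkn1a fell by 4.10 on the log2 scale.

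Of 19 clock genes 11 were higher and 5 lower at 12 weeks (12 and 5 when adjusted over the list alone), with an adjusted p of 5.34e-05 for the list (adjusted p = 0.319 with an estimated correlation). Clock genes also changed between these ages in wild type, the other way. Of 15 phase genes 10 passed there, 3 that peak with Arntl higher and 7 that peak with Dbp lower. A fixed slide block gave 2 clock genes higher and 6 lower in wild type, with a median of -0.48. Of 12 lipid droplet genes 5 were higher and 1 lower (9 and 1 when adjusted over the list alone): Cidec rose by 2.58 (its other probe, at 1.14, did not pass), Mogat1 by 1.88 and Fitm1 by 1.39, while Lpl, the lipoprotein lipase gene, was lower at -1.33. The list had an adjusted p of 0.00038 (adjusted p = 0.864 with an estimated correlation). Of 30 PPAR-alpha targets 5 were higher and 1 lower (13 and 1 when adjusted over the list alone), with Ppara itself at 0.76 and Pdk4 at -1.93 and an adjusted p of 0.00038 (adjusted p = 0.864 with an estimated correlation). Lists of type I interferon response, stellate cell and matrix markers and acute phase genes passed with medians of -0.21, -0.19 and -0.28, each with an adjusted p = 0.864 with an estimated correlation, and in the acute phase list Socs3, a feedback inhibitor of cytokine signalling, rose by 2.65. The list of stellate cell and matrix markers did not pass within slide 2 alone (adjusted p = 0.0628) or with the slide as a fixed block (adjusted p = 0.0612), and the other 5 lists did.

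In all, 1529 genes passed between ages in the knockout, 881 higher and 648 lower at 12 weeks, and 1198 passed in a fit of the slide 2 arrays alone. The named rises also held Usp2, Fmr1nb, Tchh, Wee1, Flacc1, Myc and Prr18, and the named falls Loxl4, Grk5, Meox1, Igf2bp3 and Acsm2. Leaving out single arrays gave 611 to 908 genes.

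The difference between genotypes itself differed between ages for 2287 genes, 1234 with a more positive and 1053 with a more negative difference at 12 than at 6 weeks. Among the most positive were those in Ciart (10.76 ± 0.68, SE), Dbp (8.06 ± 0.36), Cyp2b13 (7.71 ± 0.95) and Usp2 (7.14 ± 0.41). Among the most negative were those in Elovl3 (-7.12 ± 0.48), Arntl (-6.31 ± 0.53), Cdkn1a (-5.31 ± 0.40), Nat8f5 (-4.83 ± 0.51) and Tubb2a (-4.80 ± 0.42). For Ciart and Cyp2b13 in the 6-week knockout and Cdkn1a in the 6-week wild type 0 arrays were well above background, so these 3 values are fitted ones and not measured sizes. The difference for Il18 was 0.20 ± 0.16 and did not pass (adjusted p = 0.473). With the slide as a block 1533 genes passed, and the 9 genes named here with a passing difference were among them.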

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

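The tests on clock genes, sex-biased genes and genes around Il18 were chosen after the results were seen, and the test of the difference between ages, the list tests and the counts of splits were planned.

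The genotype difference differed between ages, by the test of that difference, for 2287 genes. The named ones were Ciart at 10.76, Dbp at 8.06, Cyp2b13 at 7.71 and Usp2 at 7.14 on the positive side, and Elovl3 at -7.12, Arntl at -6.31, Cdkn1a at -5.31, Nat8f5 at -4.83 and Tubb2a at -4.80 on the negative side (12 minus 6 weeks, log2). The values of Ciart, Cyp2b13 and Cdkn1a are fitted ones and not measured sizes, since a 6-week group was not well above background. Lists passed the same test with a preset correlation, with these medians: circadian clock 1.49, female-biased liver genes 2.86, male-biased liver genes -1.49, lipid droplet genes 0.87, xenobiotic metabolism 0.47, cell cycle -0.73 and Kupffer cell markers -0.48. None passed with an estimated correlation (adjusted p = 0.17, 0.117, 0.117, 0.62, 0.897, 0.897 and 0.897). Blocking on the slide gave medians of 1.74, 3.28, -1.24, 1.08, 0.59, -0.38 and -0.40 in the same order. In that fit the cell cycle genes with a more negative difference numbered 2 and not 9, and the Kupffer cell list, with 0 genes and not 2, did not pass (adjusted p = 0.0983).

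The 6 arrays of a comparison of 2 groups make 10 splits, too few for a share under 0.05. The labelled split gave 4658 genes for the genotypes at 6 weeks, 1815 for the genotypes at 12 weeks and 1529 for the ages in the knockout, with 0 genes as the highest of the other splits in each, and 1997 for the ages in wild type, with 1 gene as the highest other. For the average over ages and for the difference between ages, 100 of the 200 splits within each age were drawn, the labelled one included, and 1 of the 100, the labelled one, gave as many genes. The labelled split gave 4547 genes for the average, with 1493 as the highest other. For the difference it gave 2287, with 2030 as the highest other. These highest values came from the 13 drawn splits that kept the 6-week groups as labelled, a split that also follows the slide. Splits that mixed the 6-week groups gave at most 44 and 33 genes, and with the slide as a block the counts were 392 and 1533. The share of 1 in 100 therefore rests on the 6-week groups. The drawn splits that kept those groups are too few for a share under 0.05. Chance thus stays open for what the 12-week groups add to either count. The split that turns the 12-week groups over was not among those drawn; by construction it exchanges the counts, with 4547 genes for the difference and 2287 for the average.

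Clock genes differed between genotypes at 6 weeks in opposite directions: of 14 phase genes that passed, the 4 that peak with Arntl were higher in the knockout and the 10 that peak with Dbp were lower. A difference between slides as the only source is argued against by the knockout groups, both on slide 2, between which 15 clock genes passed within that slide. That comparison holds no wild type array. A part of the slide in the genotype difference at 6 weeks therefore stays open. A different clock time at killing needs the 2 phases to move apart, and 100% of the phase genes that passed did so at 6 weeks, as they did in the comparisons of ages in either genotype. An effect of the knockout on the clock at 6 weeks predicts the same, including the difference of -6.82 in Dbp, and cannot be told apart from clock time because the labels give no time of killing. Both may contribute, and clock time stays open in every comparison; at 12 weeks the 7 phase genes that passed all peak with Dbp and were higher, which does not test whether the phases moved apart.

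Sex-biased liver genes set the 6-week wild type apart: 23 of 27 passed between genotypes at 6 weeks and 21 between ages in wild type, against 3 between ages in the knockout and 3 between genotypes at 12 weeks. In a fit with the slide as a block, which rests on 1 wild type array, 8 male-biased and 5 female-biased genes passed between genotypes at 6 weeks, and 9 and 7 between ages in wild type. Female animals in that group are argued against by the Y-linked gene Ddx3y, which differed from the mean of the other groups by -0.207 on the log2 scale and was well above background on 12 of 12 arrays, while Xist was so on 0 arrays. Over the sex-biased genes the 12-week wild type arrays of slide 2 differed from that of slide 1 by a ratio of -0.0918 to the 6-week difference, against 1 for a slide effect, but 1 array on slide 1 excludes nothing and the slide stays open. An age difference particular to wild type, which the 3 genes in the knockout would fit, cannot be told apart from another difference of these 3 animals, such as their cohort.

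Genes that passed in the same direction at both ages were concentrated around Il18: 33 of 447 genes within 20 Mb, Il18 aside, against 306 of 21434 elsewhere (odds ratio 5.50, Fisher's exact test, two-sided p = 1.27e-13). A difference between slides is argued against at 12 weeks for the 23 of the 33 (69.7%, exact binomial 95% interval 51.3 to 84.4) that passed within slide 2. The 33 genes were chosen for passing on arrays that include those of slide 2, so part of this share is built in. The interval also treats the genes as independent. Linked DNA of another strain carried along with the targeted allele needs a decline with distance, and the odds ratio was 12.2 within 5 Mb, 6.14 from 5 to 10 Mb and 1.36 from 10 to 20 Mb. Probe sequence variants stay open: of the other probes of these genes 4 of 8 (50%, interval 15.7 to 84.3) passed in the same direction and 1 in the opposite one. Changes in Sorl1, Nxpe4, Fxyd6, Apoa4, Tmem25, Tex12, Bco2 and Cd3g may therefore follow the flanking DNA and not the loss of interleukin-18, which was not tested, nor was an effect of the deletion on its neighbours.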

How the results depend on the processing

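Among the named genes, 0 reversed direction under any alternative; of the 53 list shifts, only the test of the cell cycle list at 6 weeks pointed the other way, with the slide as a fixed block, where its median stayed just above 0 (0.0115, adjusted p = 0.516). Il18 passed under every alternative run for it, with averaged differences from -2.48 to -2.22. With the slide as a fixed block, 589 genes passed at 6 weeks, 392 on average over ages and 728 between ages in wild type, and as a random block 1226, 986 and 1077; the fixed block leaves 1 wild type array to link the slides, and 46 of 109 named genes at 6 weeks and 40 of 124 on average still passed. Fits chosen after seeing the data gave 747 genes for the genotypes at 12 weeks on slide 2 alone and 294 for the ages in wild type on slide 1 alone, both with fewer arrays. Without a filter on dim probes, which raises the genes tested to 36095, 825 genes passed at 12 weeks, 3015 on average, 1230 between ages in wild type, 730 between ages in the knockout and 1341 for the difference between ages. With only the groups compared, 377 passed at 12 weeks and 400 between ages in wild type, the comparisons that hold the 12-week wild type. The same fit gave 5445 at 6 weeks and 1423 between ages in the knockout. Fewer arrays for the spread alone therefore do not account for the lower counts. These rest on a spread shared with the other groups. A minimum of 1.5-fold, which can only remove genes, left 2343 at 6 weeks, 812 at 12 weeks, 1057 on average, 1123 between ages in wild type and 873 in the knockout. Quantile normalization, normexp correction, the other choices of probe, the trended variances, the deposited value table and the filter on all 12 arrays kept every count within 1.5 times. The list shifts numbered 53 of 204 tests, and 2 with an estimated correlation. With fry 31 passed, of which 25 were among the 53 with the same direction. With the slide as a fixed block 60 passed, of which 41 were among the 53 with the same direction. The cause was not tested for any change in the list calls or with the slide as a block.

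Leaving out single arrays gave 2617 to 3138 genes at 6 weeks, 681 to 2069 at 12 weeks, 2819 to 5383 on average, 989 to 3901 between ages in wild type, 611 to 908 in the knockout and 1566 to 3369 for the difference between ages. Counts moved by over 1.5 times without the following arrays. At 6 weeks these were wild type replicates 1 (3024), 2 (2617) and 3 (2867) and knockout replicates 1 (2949) and 2 (2644). At 12 weeks they were knockout replicates 1 (726), 2 (1022) and 3 (681), and on average 6-week knockout replicate 2 (2913) and 12-week knockout replicates 1 (2819) and 3 (2886). Between ages in wild type they were 6-week replicates 1 (1144), 2 (1154) and 3 (1058) and 12-week replicates 1 (3901) and 2 (989). Between ages in the knockout they were 6-week replicates 1 (805), 2 (828) and 3 (853) and 12-week replicates 1 (908), 2 (611) and 3 (713).

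The replicate numbers showed no clear pairing of the arrays. Over 18 pairs of arrays with the same number the correlation of their deviations from the group means ran from -0.086 to 0.18. It was over 0.1 in 2 pairs, and 6 of 12 arrays correlated best with an array of their own number. With the replicate block, 4058 genes passed at 6 weeks, 1420 at 12 weeks, 3999 on average, 1671 between ages in wild type, 1310 in the knockout and 2014 for the difference between ages, and 53 list shifts. The averaged difference of Il18 was -2.44 with the replicate block.

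Signal over background limits genes that were dim in a group: for these the fold is a bound, and genes whose probes were all left out as dim were tested only in the fit without that filter, where 3218 genes passed at 6 weeks, 2749 of them shared with the filtered fit.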

Other observations

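The tests in this part were chosen after the results were seen. The 12-week wild type stood apart from the other 9 arrays by over 1 log2 unit in 14 genes, 9 higher and 5 lower, a criterion and names chosen after their values were seen. Erdr1, an erythroid differentiation regulator gene, lay 4.22 log2 units below the lowest of the other arrays, Lrtm1 1.87 below and Nnt, the mitochondrial nicotinamide nucleotide transhydrogenase gene, 1.25 below. Among the higher ones Jchain lay 1.08 and the immediate early receptor gene Nr4a1 1.16 above every other array. By the same measure the 6-week wild type held 40 genes higher and 38 lower, among them Cyp2b13 and C6, the 6-week knockout 13 higher and 12 lower, led by Cdkn1a and Dbp, and the 12-week knockout 2 higher, among them Mogat1, and 2 lower, among them Igfbp1.

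The comparison of genotypes at 6 weeks and that of ages in wild type share the 6-week wild type arrays. Over these, 1249 genes passed in the same direction, against 211 for independent lists. Simulations of unchanged groups gave 0, but without a true change almost no gene can pass. That count therefore sets no expectation for the shared arrays. Across genes the correlation was 0.728, against 0.497 simulated, and the covariance 0.182, against 0.0218 simulated, a difference of 0.16. The shared group cannot be split into parts of at least 2 arrays, so part of the excess in the count may come from the shared arrays. A slide effect was tested as an explanation of the 4658 genes at 6 weeks. In the 12-week wild type, arrays of slide 2 differed from that of slide 1, in the direction of the 6-week difference, by a ratio of 0.185 to its median size (0.168 to 0.203 on resampling genes), against 1 for a slide effect alone. With replicate 2 or 3 set apart in its place, the ratios were -0.23 and 0.029. For the 948 genes that differed at least 2-fold the ratio was -0.00459 (-0.0263 to 0.0481). The intervals resample genes and not arrays. With 1 array of this group on slide 1, the slide cannot be told apart from genotype at 6 weeks, whatever the size of the difference. It may account for part of the differences.

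Outside the 20 Mb around Il18, 306 genes passed in the same direction at both ages, against 190 for independent lists. With the 12-week comparison limited to slide 2, 120 did so, against 73.9. Over all genes, the 20 Mb included, genes that passed in opposite directions were in excess as well. Of these, 95 were higher at 6 weeks and lower at 12 weeks, against 66.3, and 157 the reverse, against 117. In the fit of all arrays both comparisons use the same spread for each gene, so the lists are not independent. The excess in the same direction alone therefore does not show a shared effect of genotype.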
